A study of Mus musculus with 4 samples.

How the data were processed

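Bulk RNA sequencing of mouse liver tumours was analysed from the gene count tables of 4 libraries, 2 from mice given phosphate-buffered saline (PBS 1 and PBS 2) and 2 from mice given Akkermansia muciniphila (AKK 1 and AKK 2). Per the labels, total RNA was taken from the tumours and sequenced on an Illumina instrument as pairs of 151 bp reads, and the libraries of a group are biological replicates. The labels give no batch, but the names of the deposited tables follow different patterns in the PBS and AKK groups. If these mark separate cohorts, cohort and feeding cannot be told apart in any comparison here. The labels do not say whether the replicates are tumours of separate mice, so p-values measure the spread between these samples. The deposited values are raw read counts per gene, in the layout of STAR's gene counting, and the submitters' processing notes name STAR 2.5.2 and RSEM 1.2.31. The genome build and annotation release are not given in the sources used here, so no coordinates are printed. Such tables count reads that map to 1 place in the genome and overlap 1 gene. Reads of near-identical genes are therefore lost or split, which makes single members of the Serpina1, Mup, Saa, Orm, haemoglobin, ribosomal protein, histone and immunoglobulin families uncertain, as well as mitochondrial genes with nuclear copies (mt-Co2, mt-Co3 and mt-Atp6).

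Each table holds counts without regard to strand and counts on either strand. The column for the gene's own strand held 95.4 to 96.2% of the reads assigned by strand and was used, by the rule that a column above 80% in every library is taken. The 4 summary rows of each table, which name no gene, were left out of library sizes and tests. They held 12.3, 12.1, 8.97 and 9.92% unmapped, 4.20, 4.72, 6.66 and 4.98% multimapping, 12.1, 13.4, 13.5 and 11.4% outside genes and 1.20, 1.18, 1.37 and 1.33% ambiguous reads in PBS 1, PBS 2, AKK 1 and AKK 2. Of 48526 gene identifiers, 48058 matched a symbol in a table of gene names, by identifier without its version.

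Genes were compared between AKK and PBS with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit in its legacy form, glmQLFTest, two-sided), with TMM scaling, the filterByExpr filter, group as the only term and Benjamini-Hochberg adjustment at 0.05 over the 17479 genes kept. Log2 fold changes are AKK minus PBS and use a prior count of 0.125. Their standard errors (SE) were derived from the F statistic. CPM values are scaled by TMM, and 3 reads, the count that 0 observed reads allow, are worth 0.0514 to 0.0631 CPM. That floor covers counting error only. Medians of lists were the same to 2 decimals with members at 0 in a group set to this floor.

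Before the data were examined, 45 gene lists were fixed, covering pathways and markers of cell types that a liver tumour can hold. Lists with at least 5 members kept were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg adjustment at 0.05 over 41 lists), which compares a list's members with all other genes. Of the other 4 lists, 3 had fewer kept members, and the sex-linked genes served only to describe the animals. Adjustment over a list alone was done for its members. The genes named in the text follow a rule fixed at the same time, and not every gene that it picked is printed. Among genes past the threshold with a mean log2 CPM of at least 1 and both AKK libraries on 1 side of both PBS libraries, it takes the 12 protein-coding genes with the largest change per direction, without predicted genes. Where fewer than 5 passed, genes with the smallest p bring the number to 5. From each list it takes up to 4 members past the threshold or, where none passed, the 2 with the smallest p. It also takes 11 key genes (Pdcd1, Cd274, Cd8a, Cd4, Foxp3, Ly6c2, Ly6g, Arg1, Mrc1, Afp and Alb). Every other gene named was chosen after its values were seen.

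Alternatives fixed at the same time were the size factors of DESeq2, upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 2 libraries, the replicate number as a block, the unstranded column, leaving out each library in turn, DESeq2 1.42.0, limma-voom (limma 3.58.1), thresholds of 0.1 and 0.01, a test against a fold of 1.5, camera with an estimated correlation, and fry. With a library left out, the lone library of its group was assumed to vary like the others. The filter was then applied anew and kept 18207 to 18779 genes. Genes with reads in 1 library could enter, so lists did not keep the same members. The edgeR 4 form of the quasi-likelihood test was added after seeing the data. The gene test and the list test were tested on simulated counts with 2 libraries per group and 17479 genes, in 5 simulations of this comparison. The edgeR test called 79.2% of genes changed 4-fold and 100% of those changed 32-fold, with 17.4 false calls per simulation. DESeq2 called 92.2% and 100% (461 and 500 of 500 genes over the 5 simulations) with 78.6 false calls per simulation. The share of false calls was above 0.05 in both tests, and larger in DESeq2. Changed genes had a mean of at least 2 CPM. These shares are not the power in the data, where edgeR called 1 of 22 hepatocyte genes at a median log2 fold change of 7.20. Camera with the preset correlation called a list of 20 genes changed 4-fold in 5 of 5 simulations, and with an estimated correlation in 0 of 5. Of 200 unchanged lists neither form called any. Simulated genes varied independently of each other, so this does not cover lists whose members vary together. In the data the estimated correlation ran from -0.06 (fatty acid oxidation) to 0.99 (skeletal muscle).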

Results

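Liver tumours of C57BL/6 mice were compared between animals fed Akkermansia muciniphila (Akk), a mucin-degrading bacterium of the gut, and animals given PBS. Per the series' design text, 5000000000 colony-forming units of Akk or PBS were given for 2 weeks before and throughout 2 weeks of a methionine- and choline-deficient (MCD) diet, a diet that produces fatty liver. Luciferase-labelled RIL-175 cells, a mouse hepatoma line, were then implanted into the liver. Feeding paused for 6 days after surgery and went on until the end. The comparison asks how feeding Akk changes the transcriptome of the tumours, with the immune cells of the tumour as its stated focus. The 4 libraries held 52500328 (PBS 1), 48912489 (PBS 2), 55360237 (AKK 1) and 59027227 (AKK 2) reads on genes. Across 17479 genes, which are not independent replicates, log2 CPM correlated with r = 0.973 between the PBS libraries, 0.974 between the AKK libraries and 0.925 to 0.964 between groups. AKK 1 stood apart in make-up, with 3.92% mitochondrial and 6.69% ribosomal protein reads, against 1.64 to 2.33% and 3.50 to 4.23% in the other libraries.

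Fgb (ENSMUSG00000033831.5), the beta chain of fibrinogen made by hepatocytes, rose 416-fold in AKK tumours, from 0.112 and 0.189 CPM in PBS 1 and PBS 2 to 75.4 and 50.8 CPM in AKK 1 and AKK 2 (log2 fold change 8.70, SE 0.41, adjusted p = 0.0160, n = 2 per group, higher in 2 of 2 AKK libraries). It was the 1 gene past the threshold in edgeR, which called 0 genes lower. The next smallest p-values among higher genes belonged to plasma proteins of the liver, all short of the threshold in edgeR. They were the protease inhibitor Pzp (log2 fold change 8.35, adjusted p = 0.0556), the fibrinogen gene Fgg (8.29, 0.0556), the fetuin gene Ahsg (7.99, 0.111) and the complement protease Cfi (5.80, 0.111). The 5 lower genes with the smallest p also missed it in edgeR. The scavenger receptor gene Scarf2 lay at 23.7 and 24.4 CPM in PBS against 3.57 and 2.57 in AKK (adjusted p = 0.120). Lrrc15, a marker of activated fibroblasts, lay at 15.7 and 11.8 against 0.230 and 0.634 CPM (0.173). Lmbrd2 (log2 fold change -2.26), the imprinted gene Peg3 (-3.78) and Ttll7 (-3.72) each had an adjusted p of 0.173. DESeq2 called all of these genes, with adjusted p of at most 2.90e-17 for the higher (Cfi) and 1.11e-09 for the lower (Lmbrd2). At an unadjusted p under 0.05 in edgeR there were 2677 genes, 1171 higher and 1506 lower, where chance gives 874. Both AKK libraries lay on the same side of both PBS libraries in 51.4% of genes, against 33.3% by chance. The count of calls depended on the test: DESeq2 called 908 genes (383 higher, 525 lower), limma-voom 0, and edgeR without a filter on low counts 631. Leaving out PBS 1 or PBS 2 gave 279 and 324 genes, and leaving out AKK 1 or AKK 2 gave 0, where Fgb had an adjusted p of 0.615 and 0.152.

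Genes of adult hepatocytes rose together in the AKK tumours. All 22 measured members lay higher in both AKK libraries than in both PBS libraries, with a median log2 fold change of 7.20 (camera adjusted p = 1.21e-48, adjusted p = 0.750 with an estimated correlation). The 22 passed when adjusted over the list alone, and over all genes edgeR called 1 (Fgb) and DESeq2 21. The median member read 0.0375 and 0.0841 CPM in PBS 1 and PBS 2. Members at such levels passed the filter only through their AKK reads, which favours a rise in AKK. Albumin (Alb), the main plasma protein, read 0.2999 and 0.988 CPM in PBS 1 and PBS 2 against 156 and 25.4 CPM in AKK 1 and AKK 2. Apolipoprotein Apoa1 read 0.187 and 0.694 against 103 and 15.0 CPM. Acute phase proteins, which the liver secretes in inflammation, rose as well, with 13 of 15 members positive and a median of 5.44 (adjusted p = 2.15e-21, adjusted p = 0.750 with an estimated correlation). Of these, 12 passed when adjusted over the list alone, and over all genes edgeR called 0 and DESeq2 11. Orm1 lay at 0.112 and 0.147 against 26.8 and 5.17 CPM, and Itih4 at 0.169 and 0.105 against 23.7 and 4.98 CPM. Markers of Kupffer cells, the resident macrophages of the liver, rose with a median of 4.87, with 7 of 9 members positive and 6 above both PBS libraries (adjusted p = 1.15e-05, adjusted p = 0.750 with an estimated correlation). Of these, 4 passed when adjusted over the list alone, and DESeq2 called 4 over all genes. Vsig4 had 1 and 1 reads in PBS and 49 and 25 in AKK, and Cd5l had 2 and 0 against 251 and 49. Vsig4, Cd5l, Orm1 and Itih4 likewise passed the filter only through their AKK reads. In all 3 lists the AKK 1 value exceeded the AKK 2 value at the median member (23.2 against 2.89 CPM, 15.2 against 4.98 and 4.44 against 0.548). Without AKK 1 the medians were 5.20, 3.82 and 1.70, and all 3 lists still passed.

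**Figure D1:**
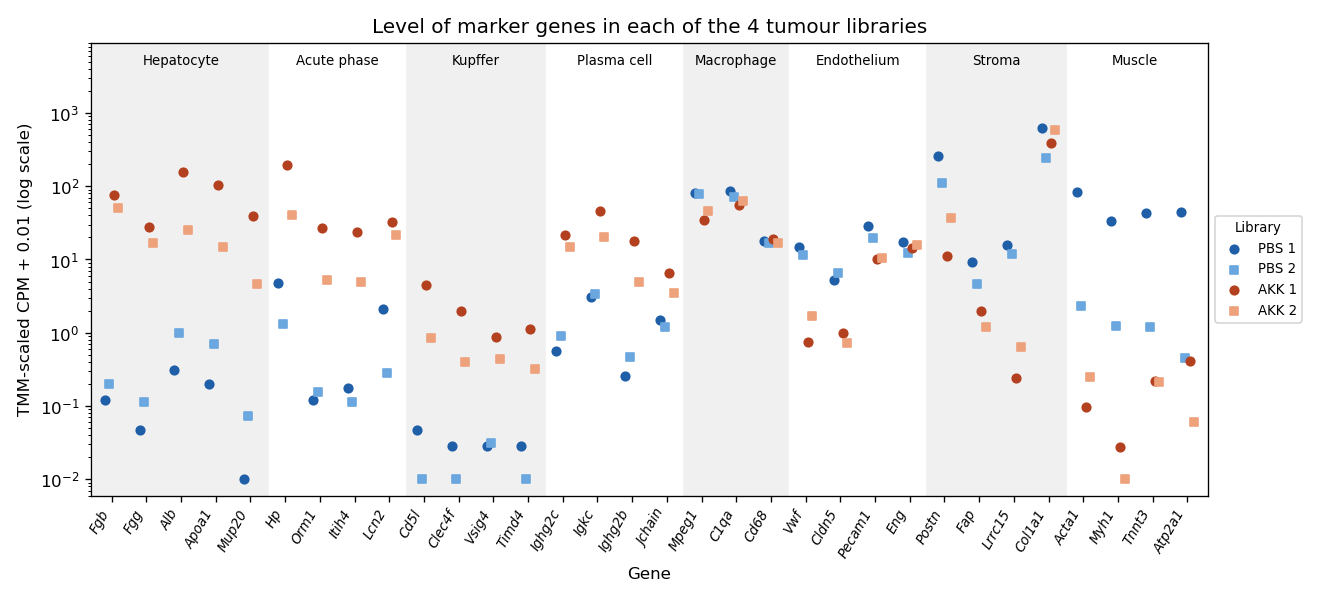
TMM-scaled CPM plus 0.01 (log scale) of 32 marker genes picked for display after their values were seen, grouped by cell type or process, with 1 point per library (2 PBS libraries in blue, 2 AKK libraries in red to orange). The hepatocyte, acute phase and Kupffer genes drawn lie higher in both AKK libraries (Alb 156 and 25.4 CPM against 0.2999 and 0.988), and muscle genes stand out in PBS 1 (Acta1 83.7 CPM).

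Plasma cell genes rose in the AKK tumours, with 9 of 9 members positive and a median log2 fold change of 1.88 (camera adjusted p = 1.72e-10, adjusted p = 0.750 with an estimated correlation). Of these, 6 passed when adjusted over the list alone, and over all genes edgeR called 0 and DESeq2 5. Without PBS 2 the median was 3.38. The antibody heavy chain gene Ighg2c read 0.562 and 0.883 CPM in PBS against 21.6 and 14.7 in AKK (log2 fold change 4.65, SE 0.42, adjusted p = 0.111). The light chain gene Igkc read 3.09 and 3.41 against 46.0 and 20.1 CPM (3.35, SE 0.45, adjusted p = 0.182). Of 346 variable segments of immunoglobulins, 10 passed the filter. These rose by a median of 3.08, 6 of them past the threshold when adjusted over the list alone (adjusted p = 1.95e-07, adjusted p = 0.750 with an estimated correlation). They had few reads: Igkv19-93 had 3 and 1 reads in PBS and 33 and 74 in AKK. The median member read 0.0375 and 0.0526 CPM in PBS, so members at such levels passed the filter through their AKK reads. That selection favours a rise in AKK. The B cell list, with 5 members, did not pass (median 1.13, adjusted p = 0.394). Its value rested on AKK 1, since Ighm read 0.562 and 0.526 CPM in PBS against 5.70 and 0.993 in AKK. The B cell median was -0.42 without AKK 1, 2.84 without AKK 2 and 1.71 without PBS 1. The fits without AKK 2 and without PBS 1 also held members that entered through AKK 1. One was Ms4a1, with 0, 0, 23 and 0 reads in PBS 1, PBS 2, AKK 1 and AKK 2.

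T cell genes rose with 17 of 18 members positive and a median of 0.89 (camera adjusted p = 0.00909, adjusted p = 0.827 with an estimated correlation), but 0 members passed when adjusted over the list alone. Levels were low: Cd2 read 0.187 and 0.231 CPM in PBS against 1.06 and 0.445 in AKK, and Cd5 read 0.112 and 0.0631 against 0.478 and 0.223. This call ended without AKK 1 (median 0.05, adjusted p = 0.46) and without PBS 1 (0.46, adjusted p = 0.25), and the median was 1.42 without AKK 2 and 1.38 without PBS 2. CD8 and cytotoxic lymphocyte genes did not pass, with 9 of 12 positive and a median of 0.49 (adjusted p = 0.534), although they did without PBS 2 (1.26, adjusted p = 0.00910). Cd8a read 0.956 and 3.26 CPM against 3.93 and 2.62, and the granzyme gene Gzma 1.95 and 3.53 against 0.159 and 1.25. Helper and regulatory T cells (median 0.74, adjusted p = 0.515) and NK and NKT cells (median 0.04 with a downward test and mean, adjusted p = 0.725) did not pass. Cd4 read 0.825 and 0.442 against 1.36 and 1.06 CPM, and Foxp3, the transcription factor of regulatory T cells, 0.281 and 0.168 against 0.743 and 0.188 CPM. Immune checkpoint genes did not pass (median -0.24, adjusted p = 0.139), except without PBS 1 (-0.48, adjusted p = 0.0050). Pdcd1, the gene of PD-1, read 0.525 and 0.988 CPM in PBS against 0.991 and 0.736 in AKK, and its ligand Cd274 read 16.2 and 43.9 against 18.8 and 14.3. The 2 members with the smallest p were Vtcn1 (8.85 and 13.3 against 1.15 and 3.07 CPM) and Entpd1 (15.6 and 14.8 against 5.71 and 7.84 CPM), with adjusted p of 0.196 and 0.211 in edgeR and 0.000552 and 0.0135 in DESeq2.

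Macrophage genes fell in the AKK tumours by a median log2 fold change of -0.41, with 12 of 16 members negative (camera adjusted p = 0.0169, adjusted p = 0.822 with an estimated correlation) and 0 past the threshold when adjusted over the list alone. Mpeg1, a pore-forming protein of macrophages, read 80.3 and 78.2 CPM in PBS against 34.3 and 45.3 in AKK. The call ended without PBS 1 (median -0.12, adjusted p = 0.35) and without AKK 2 (-0.43, adjusted p = 0.083). Genes of M2-associated macrophages (median -0.14, adjusted p = 0.636), M1-associated macrophages (0.12, adjusted p = 0.641), monocytes and monocytic myeloid-derived suppressor cells (0.34, adjusted p = 0.361), neutrophils and granulocytic suppressor cells (0.34, adjusted p = 0.918) and dendritic cells (0.27, adjusted p = 0.636) did not pass. In the monocyte list 2 members passed as higher and 2 as lower when adjusted over the list alone. The 2 higher members were Hp (4.72 and 1.30 against 195 and 40.4 CPM), which the acute phase list also holds, and Cd14 (17.1 and 19.8 against 40.9 and 30.3 CPM). Arg1 read 90.1 and 66.4 CPM against 63.9 and 49.8, and the mannose receptor Mrc1 470 and 363 against 360 and 341. The neutrophil gelatinase gene Mmp9 read 71.3 and 15.3 against 8.12 and 11.8 CPM. Ly6c2 (1, 4, 32 and 5 reads in PBS 1, PBS 2, AKK 1 and AKK 2) and Ly6g (0 reads in each, which allows up to 0.0631 CPM) were below the filter. Toll-like receptor and NF-kB genes (median 0.21, adjusted p = 0.210) and myeloid-recruiting chemokines (0.27, adjusted p = 0.271) did not pass. The monocyte chemokine Ccl2 read 4.12 and 4.86 against 16.7 and 7.76 CPM.

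At the median member, both interferon lists differed more between the PBS tumours than between the groups. At the median member of the interferon gamma and antigen presentation list, PBS 1 and PBS 2 read 34.3 and 77.3 CPM and AKK 1 and AKK 2 57.3 and 41.6 CPM. That list had a median log2 fold change of -0.36 (camera adjusted p = 0.470) and the type I interferon list -0.19 (adjusted p = 0.636). Gbp2, an interferon-induced GTPase, read 73.5 and 574 CPM in PBS 1 and PBS 2 against 73.3 and 109 in AKK 1 and AKK 2. Nlrc5, a regulator of MHC class I genes, read 34.3 and 72.4 against 29.9 and 21.6 CPM. Of the type I list, Oas2 lay higher in both AKK libraries, at 2.34 and 6.41 against 26.3 and 7.45 CPM. Mx1 lay lower in both, at 18.5 and 14.4 against 11.5 and 4.62 CPM (edgeR adjusted p = 0.306 for Oas2 and 0.355 for Mx1). The directions of both lists turned on which PBS library was compared. Without PBS 1 they were lower in AKK (-0.84, adjusted p = 3.33e-13, and -0.68, adjusted p = 4.15e-06), and without PBS 2 they were higher (0.61, adjusted p = 0.000171, and 0.70, adjusted p = 0.00136).

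Skeletal muscle genes fell in AKK with 9 of 9 members negative and a median log2 fold change of -6.60 (camera adjusted p = 2.03e-07, adjusted p = 0.750 with an estimated correlation), 8 of them past the threshold when adjusted over the list alone. Most of that difference lay in PBS 1. The skeletal actin gene Acta1 read 83.7 CPM in PBS 1, 2.29 in PBS 2, 0.0885 in AKK 1 and 0.240 in AKK 2, and without PBS 1 the list's median was -2.31 (adjusted p = 2.3e-07). Endothelial genes fell by a median of -0.90 with 13 of 16 negative (adjusted p = 7.78e-05, adjusted p = 0.750 with an estimated correlation). When adjusted over the list alone, 5 members passed as lower and 1 as higher. Von Willebrand factor (Vwf) read 15.0 and 11.6 CPM in PBS against 0.743 and 1.70 in AKK, and the tight junction gene Cldn5 5.30 and 6.48 against 0.991 and 0.719, while Stab2, a receptor of liver sinusoids, read 0.131 and 0.126 against 2.65 and 0.822. The endothelial call ended without PBS 1 (-0.70, adjusted p = 0.053) and without AKK 2 (-0.80, adjusted p = 0.077). Fibroblast and stellate cell genes did not pass (median -0.49, adjusted p = 0.1254). Their direction turned without PBS 1 (0.70, adjusted p = 0.253), and without PBS 2 they passed (-1.26, adjusted p = 5.73e-07). The matrix protein periostin (Postn) read 255 and 111 against 11.1 and 36.8 CPM, and Fap 9.32 and 4.60 against 2.00 and 1.18. The matrix remodelling list did not pass (-0.20, adjusted p = 0.456), with Col6a3 at 235 and 128 against 67.1 and 93.9 CPM.

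Cholesterol synthesis genes fell in AKK, with 22 of 22 members negative, 17 of them below both PBS libraries, and a median log2 fold change of -0.39 (camera adjusted p = 6.97e-05, adjusted p = 0.750 with an estimated correlation). When adjusted over the list alone, 2 passed. The median member read 109 and 106 CPM in PBS against 72.8 and 98.3 in AKK 1 and AKK 2, and without AKK 1 the list's median was -0.25 (adjusted p = 0.0020). Lanosterol synthase (Lss) read 79.2 and 82.6 CPM against 35.2 and 39.99 (log2 fold change -1.11, SE 0.18, adjusted p = 0.182), and the sterol carrier Stard4 209 and 181 against 74.0 and 107 CPM (-1.11, SE 0.24, adjusted p = 0.191). Genes of fatty acid oxidation rose by a median of 0.15 (adjusted p = 0.0454, adjusted p = 0.750 with an estimated correlation), and the call ended with the unstranded counts (adjusted p = 0.0679). The median was 0.42 without AKK 2, 0.36 without PBS 1 and 0.44 without PBS 2. When adjusted over the list alone 3 passed. The thiolase gene Acaa1b read 0.862 and 1.98 against 15.9 and 7.14 CPM. Methionine, choline and one-carbon genes (median 0.07, adjusted p = 0.0584), bile acid genes (0.32, adjusted p = 0.0878) and fatty acid synthesis genes (-0.14 with a mean of 0.02, adjusted p = 0.636) did not pass. When adjusted over the list alone, 3 methionine and choline genes passed as higher and 0 as lower, and 2 were lower at an unadjusted p under 0.05. The 3 higher genes were near 0 in PBS, like the hepatocyte genes: choline dehydrogenase (Chdh) had 0 and 0 reads in PBS and 125 and 63 in AKK, Bhmt 0 and 1 against 624 and 70, and Mat1a 1 and 5 against 1003 and 109. The list's mean was 1.78. The exporter gene Abcc2 read 0.0375 and 0.357 against 6.37 and 2.60 CPM. The bile acid median was 4.02 without AKK 2, 3.35 without PBS 1 and 2.93 without PBS 2, but not over the same members. The filter, applied anew, then kept genes such as Cyp7a1 (0, 0, 84 and 0 reads in PBS 1, PBS 2, AKK 1 and AKK 2). Slco1a1 (0, 0, 30 and 0 reads) entered likewise through AKK 1, and such entries favour a rise in AKK.

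Hepatoma and oncofetal genes fell by the list test, with a median of -0.19 and 7 of 11 negative (camera adjusted p = 0.0231, adjusted p = 0.750 with an estimated correlation). When adjusted over the list alone, 3 passed. Members differed in direction, with 4 positive. The imprinted transcript H19 read 58.1 and 9.27 CPM in PBS against 1.54 and 1.59 in AKK, and Dlk1 had 26 and 23 reads in PBS and 0 and 0 in AKK. Alpha-fetoprotein (Afp) read 7.18 and 11.1 against 8.55 and 10.3 CPM. The call ended without AKK 1 (0.15 with a downward test, adjusted p = 0.66), without PBS 1 (-0.23, adjusted p = 0.071), with the stricter filter (adjusted p = 0.40) and without a filter (adjusted p = 0.10), and the median was -0.64 without AKK 2. Cell cycle genes (median 0.13, adjusted p = 0.146), hypoxia and glycolysis genes (-0.06 with a mean of 0.05, adjusted p = 0.918), oxidative stress genes (0.33, adjusted p = 0.210), unfolded protein response genes (0.05, adjusted p = 0.3002), immediate early genes (-0.15, adjusted p = 0.0624), cholangiocyte genes (-0.24 with an upward test, adjusted p = 0.725) and erythroid genes (-0.54, adjusted p = 0.0760) did not pass. Of these lists' members, 3 immediate early genes passed as lower and 1 cholangiocyte gene passed in each direction when adjusted over the list alone. Catalase (Cat) read 69.6 and 63.4 against 109 and 115 CPM, and the immediate early gene Egr1 267 and 391 against 145 and 99.1 CPM. Epcam, an epithelial adhesion molecule, read 0.131 and 0.0210 against 2.25 and 3.37 CPM.

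Cytosolic ribosomal protein genes rose by a median log2 fold change of 0.55, with 83 of 84 positive (camera adjusted p = 4.74e-12, adjusted p = 0.822 with an estimated correlation), and 0 passed when adjusted over the list alone. The difference lay mostly in AKK 1, where the median member read 707 CPM against 368, 452 and 454 in PBS 1, PBS 2 and AKK 2, and without AKK 1 the median was 0.19 (adjusted p = 8.7e-05) and without AKK 2 it was 0.83. Mitochondrially encoded genes rose by a median of 0.82 with 16 of 19 positive (adjusted p = 0.000176, adjusted p = 0.822 with an estimated correlation), and again 0 passed when adjusted over the list alone. The complex I gene mt-Nd2 read 889 and 684 CPM in PBS against 2647 and 1609 in AKK, and the call ended without AKK 1 (0.31, adjusted p = 0.094). Replication-dependent histone genes fell by a median of -0.65 with 42 of 55 negative (adjusted p = 7.28e-06, adjusted p = 0.778 with an estimated correlation), 5 of them past the threshold when adjusted over the list alone. Counts were low, with the median member at 1.14 and 1.18 CPM in PBS against 0.761 and 0.497 in AKK. Hist1h2bj read 2.94 and 3.03 against 0.495 and 0.582 CPM, and the call ended without AKK 2 (-0.49, adjusted p = 0.077). In all, 15 of the 41 lists passed with the preset correlation, 9 higher and 6 lower, and 0 passed with an estimated correlation or with fry (lowest adjusted p 0.750 and 0.393). Over all genes tested, edgeR called 1 member of these lists, Fgb. Beside the counts given above, DESeq2 called 1 immunoglobulin variable segment, 1 ribosomal protein gene, 2 mitochondrially encoded genes, 3 fatty acid oxidation genes, 1 endothelial gene and 0 T cell genes as higher. As lower it called 6 muscle, 5 endothelial, 7 histone, 3 cholesterol synthesis, 3 oncofetal and 2 macrophage genes.

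**Figure D2:**
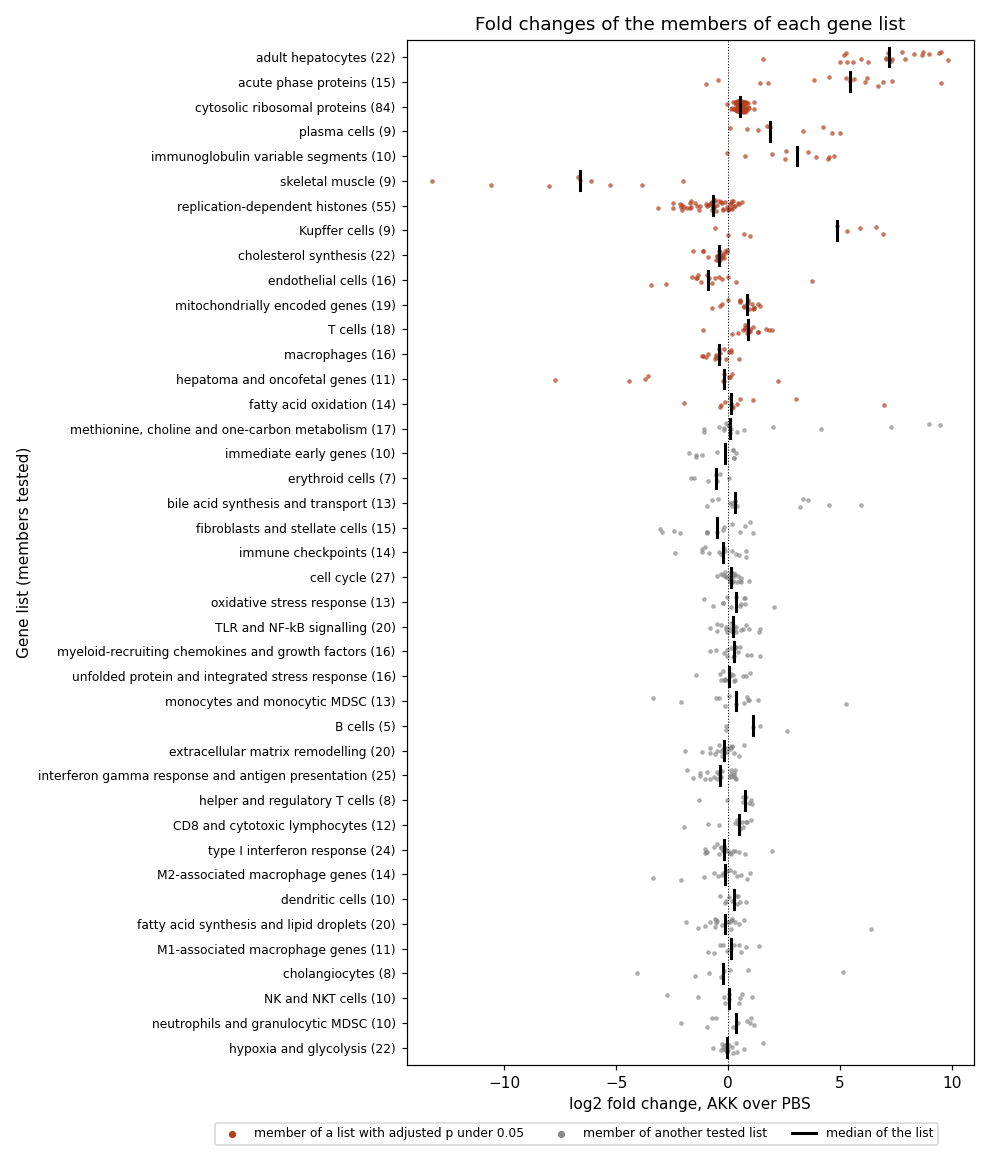
Log2 fold changes (AKK over PBS) of the members of the 41 tested gene lists, with 1 point per gene, the median as a black bar and the number of members in parentheses; points lie in red for the 15 lists past the threshold with the preset correlation. The hepatocyte list (median 7.20) and the skeletal muscle list (median -6.60) lie at the ends.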

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

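Settings fixed before the data were examined were tried one at a time, and the edgeR 4 form of the test was chosen after seeing the data. Genes changed between AKK and PBS tumours numbered 1 in the test reported above. Against that, upper-quartile scaling gave 3 genes, no filter on low counts 631, DESeq2 908, limma-voom 0 (2509 at an unadjusted p under 0.05), the edgeR 4 form 4, a threshold of 0.1 gave 3 and a threshold of 0.01 gave 0. DESeq2 size factors, the filter of 1 CPM, the unstranded column and the test against a fold of 1.5 each gave 1. Leaving out a library gave 0 to 324 genes, with 1454 and 4304 at an unadjusted p under 0.05 without AKK 1 and AKK 2, where 0 were called. The cause of these shifts was not tested, but the prior degrees of freedom of the fit were 3.87 with all libraries, 12.2 without a filter, 14.8 and 9.13 without PBS 1 and PBS 2, and 2.74 and 2.64 without AKK 1 and AKK 2. With the replicate number as a block, 209 genes were called (128 higher, 81 lower) and 19 lists. The numbers do not pair the samples by any label, and same-numbered libraries deviated from their group means with a correlation of -0.0153 across genes. Fgb kept its direction in each setting (8.36 to 9.07) and lost its call without AKK 1, without AKK 2, in limma-voom (adjusted p = 0.204) and at a threshold of 0.01. The 15 list calls were 15 with DESeq2 size factors and with upper-quartile scaling, 17 without a filter, 11 of 35 lists with the stricter filter, 14 with the unstranded column, 15 to 25 with a library left out, and 0 with an estimated correlation and 0 with fry. Other scalings moved the median of all genes by -0.015 and 0.055. Directions turned for results short of the threshold, and the cause was not tested: with the unstranded column Adrb3 was 0.17 and Foxp3 -0.81. In the list test the sign turned for hypoxia and glycolysis (medians 0.0032 with upper-quartile scaling, -0.058 with the stricter filter, -0.042 with the block, -0.052 unstranded), CD8 and cytotoxic lymphocytes (0.022, stricter filter), M2-associated macrophages (-0.069, stricter filter) and neutrophils (0.21 without a filter, -0.16 with the stricter one). With a library left out, the log2 fold change of Gbp2 ranged from -2.65 to 0.28, and others ranged from -0.27 to 2.17 for Cd79a, -1.12 to 0.78 for Adrb3, -0.51 to 1.15 for Fabp4, -1.48 to 0.038 for Msln, -0.53 to 2.16 for Wt1, -0.20 to 0.68 for Pdcd1, -0.26 to 1.70 for Foxp3 and -0.23 to 0.36 for Afp. List medians ranged from -0.68 to 0.70 for type I interferon, -0.84 to 0.61 for interferon gamma, 0.0052 to 0.55 for chemokines, -0.23 to 0.0066 for fatty acid synthesis, -0.52 to 0.16 for matrix remodelling, -0.33 to 0.28 for hypoxia and glycolysis, -0.51 to 0.51 for the unfolded protein response, 0.079 to 1.26 for CD8 and cytotoxic lymphocytes, -0.082 to 0.37 for NK and NKT cells, -0.16 to 1.12 for helper and regulatory T cells, -0.42 to 2.84 for B cells, -0.32 to 0.091 for M2-associated and 0.051 to 0.20 for M1-associated macrophages, -0.53 to 1.09 for neutrophils, -1.26 to 0.70 for fibroblasts and stellate cells, and -0.19 to 0.89 for cholangiocytes. Over the settings other than the thresholds of 0.1 and 0.01 and the test against a fold of 1.5, named genes kept direction and side of the threshold in 1084 values, passed it in 203, lost it in 3 and turned in 16. List tests did so in 384, 27, 43 and 32. Depth limits lowly expressed genes such as Pdcd1, which had 28 to 56 reads in a library.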

Other observations

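The genes outside the fixed lists, and the tests of scaling, of fibrinogen ratios, of the endothelial list, of the macrophage list and of plasma cell ratios, as well as the bar on baseline levels in the test of liver sinusoidal genes, were chosen only after the result was seen, while the sinusoidal, further hepatocyte, further muscle and imprinted lists were written before their values were looked at, except for Stab2, Mrc1 and Arg1, which the fixed lists also hold. None of the genes outside the lists named here passed the adjusted threshold in edgeR. C3, the central complement component, read 15.4 and 7.51 CPM in PBS 1 and PBS 2 against 126 and 78.0 in AKK 1 and AKK 2 (log2 fold change 3.15, SE 0.43, edgeR adjusted p = 0.182), and C4b read 4.84 and 2.38 against 27.5 and 14.7 CPM. Il1rn, the antagonist of the interleukin 1 receptor, read 14.4 and 29.5 against 66.1 and 73.0 CPM. The growth factor gene Fgf2 read 4.54 and 6.88 against 17.6 and 17.9 CPM, and the adhesion receptor Selp 10.7 and 9.99 against 76.9 and 26.9 CPM.

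Among the lower genes with the smallest p, the matrix protein Thbs2 read 70.0 and 42.3 CPM against 7.27 and 10.7, the collagen Col12a1 78.3 and 39.5 against 3.45 and 10.2, the fibroblast cadherin Cdh11 18.3 and 6.67 against 1.24 and 1.52, and the collagen receptor Ddr2 61.4 and 20.1 against 4.67 and 5.87. The collagen Col1a1 overlapped between the groups, at 624 and 242 against 387 and 577 CPM. The secreted neuronal pentraxin Nptx1 read 559 and 280 against 44.4 and 80.6 CPM. Of the sex-linked genes, the Y-linked Ddx3y read 28.6 CPM in PBS 1 and 5.61, 6.10 and 4.30 in PBS 2, AKK 1 and AKK 2, and Xist 3.30, 6.56, 3.03 and 1.75. Of lists too short to test, the mesothelial gene Msln read 217 and 631 CPM in PBS against 222 and 232 in AKK, the fat cell gene Fabp4 7.78 and 2.502 against 6.67 and 4.47, and the pancreatic protease gene Try5 had 20 and 50 reads against 2 and 0.

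Of the fixed lists, 22 of 22 hepatocyte, 13 of 15 acute phase and 6 of 9 Kupffer genes lay above both PBS libraries in both AKK libraries. Of 20 further hepatocyte genes, 18 did too (18 of 19 without Arg1, which had been seen). Their median log2 fold change was 4.53 (camera p = 7.73e-19, 0.0979 with an estimated correlation). Chance gives 16.7%, but not for genes near 0 in PBS. Those passed the filter only through their AKK reads, which fixed their side in advance. Of the 20, 6 read over 1 CPM in PBS. Among these Gc, Trf, Rbp4 and Serpinc1 lay above both PBS libraries, Arg1 lay below and Apob overlapped. Scaling and library size, which move all genes of a library alike, are argued against, since the hepatocyte median exceeded the median of all genes by 7.18 and the lowest hepatocyte gene exceeded it by 1.52 (log2). A candidate explanation is liver tissue next to the tumour in the AKK samples. It predicted that at least 50% of liver sinusoidal endothelial genes would lie above both PBS libraries. The share was 10% (Stab2 alone, chance 16.7%, and 0 of the 8 not seen before), which met the bound written against it. Of the 10 genes, 4 lay below both PBS libraries, and the median log2 fold change was -0.25. The bound was set aside after the value was seen, because 7 of the 10 genes read over 1 CPM in PBS (median 2.42, against 0.0790 for hepatocyte genes). A small share of liver could be hidden at such levels, but that share was not estimated. Of the 3 genes that read less in PBS, Stab2 lay above and Gpr182 and Wnt2 overlapped. Clec4g of the fixed endothelial list, below the filter and outside this count, had 0 and 0 reads in PBS and 30 and 5 in AKK. Liver tissue as an explanation stays open. A single source of constant make-up for fibrinogen and the other hepatocyte genes also stays open: the median AKK 1 to AKK 2 ratio of Fga, Fgb and Fgg, 1.48, lay below all 19 others (median 6.15), which met the bound set against it, but the 3 ratios (1.21 to 1.66) overlapped the lowest of the others (1.58, Ass1; 2.86 without Ass1), a criterion added after the values were seen. Of the 22 hepatocyte genes 1 read over 1 CPM in PBS, and an effect of Akk feeding on the tumour cells or on the share of liver sampled was not tested and cannot be told apart from these.

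Muscle genes lay higher in the PBS tumours, mostly in PBS 1. Endothelial genes were called lower in AKK as well, and that call was lost without PBS 1 (-0.70) or AKK 2 (-0.80, against -0.90). A candidate source is muscle tissue in the library of PBS 1, and of 11 further muscle genes fixed before they were looked at, 72.7% (8) were at least 5 times higher there than in each other library, with Ttn at 53.1 CPM against 2.63, 0.124 and 0.0685 in PBS 2, AKK 1 and AKK 2. Whether that tissue also brought the endothelial difference cannot be told apart from a difference between the groups: without PBS 1 the endothelial median was -0.70, which stays well below 0, but its adjusted p was 0.053. PBS 2 also lay above both AKK libraries for Acta1 (2.29 against 0.0885 and 0.240 CPM), and an effect of Akk feeding on the stroma was not tested.

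Plasma cell genes lay higher in both AKK tumours. A lower share of tumour cells in the AKK samples could raise all other cell types alike. The macrophage list lay at -0.41 and the endothelial list at -0.90 against 1.88 for plasma cells, which argues against such a uniform rise only. Both lower calls depended on single libraries. Their medians were -0.12 and -0.70 without PBS 1 (against 2.05 for plasma cells) and -0.43 and -0.80 without AKK 2. Muscle tissue in PBS 1 may also bear on the endothelial value. A lower share of tumour cells with liver tissue in their place need not raise all types alike, and these lists cannot decide on it. Plasma cells of the adjacent liver stay open. The median AKK 1 to AKK 2 ratio of plasma cell genes other than Sdc1 was 2.08, outside the middle part of the hepatocyte genes (4.68 to 8.99). It lay inside their full range (1.21 to 19.1), but only through the fibrinogen genes and Ass1. The lowest ratio of the other hepatocyte genes was 2.86. As hepatocyte ratios spread this widely, the comparison cannot decide. Sdc1 was left out of the plasma cell ratio because it read 355 to 541 CPM in every library. An antibody response that follows Akk feeding was not tested.

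The imprinted genes H19, Igf2, Dlk1, Peg3 and Mest lay lower in the AKK tumours, which raised the hypothesis that imprinted genes as a class lie lower. On 16 measured imprinted genes not seen before, the median log2 fold change was -0.05 (limma's camera, adjusted p = 0.711 as 1 test), with 3 above and 3 below both PBS libraries, so the hypothesis found no support.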
